A study of Mus musculus with 6 samples.

How the data were processed

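Total RNA from 6 samples of v-Abl transformed mouse pro-B cells (3 untreated, 3 treated with tamoxifen) was hybridised to gene-level microarrays. Per the labels' protocols, RNA was extracted with TRIZOL, purified on RNeasy columns, checked for integrity, and 200 ng was converted to biotinylated cRNA with a NuGen kit. The deposited values are intensity values on a linear scale, 1 per probe set and array, which the authors had already summarised. How they corrected background, summarised probes or normalised arrays is not given in the sources used here, and neither are hybridisation batches or scan dates. Array medians lay between 100.9 and 109.1 and upper quartiles between 273.1 and 298.8, so the arrays were on a similar scale but were not identical in distribution. Groups and replicate numbers were taken from the sample titles.

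Intensities were converted to log2(value + 16) and quantile normalised across the 6 arrays, because the deposited distributions differed. Every fold change is on this log2(value + 16) scale, which understates the change of dim genes. Intensities printed with an SD are the deposited linear values. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (two-sided), with Benjamini-Hochberg adjustment over all 34760 probe sets and a threshold of 0.05. Control probe sets are not marked in the files used here, so none was left out. A table of the array platform paired 21640 probe sets with 1 gene symbol, 1321 with several, and did not list 11799. Names were given only to probe sets with 1 symbol, and 0 symbols changed when updated through Entrez IDs in a RefSeq gene table of assembly GRCm38.p6. For the 954 genes with more than 1 probe set, the probe set with the highest mean stood for the gene, giving 19937 genes. No coordinates are printed because the sources used here give no genome build for the array.

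The model, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named 16 genes of the FOXO and pro-B cell literature whatever their result, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, and up to 4 members of each list past the threshold. Genes with only a clone or RIKEN style name were passed over, and fewer were named where fewer passed. Of the 16 genes, 1 is not reported here. A total of 24 gene lists were tested with camera at a preset inter-gene correlation of 0.01 on 1 probe set per gene. They cover Foxo1 targets, B cell development and signalling, cell cycle, stress, metabolism and markers of other cell types. Each list was also tested with a correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, one way. Neither test called any list (0 of 24), and the lowest adjusted p of fry was 0.0906.

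The steps were tested on simulated data. With 200 of 34760 probe sets changed in each of 10 simulations of 3 against 3 arrays, limma recovered 49.9% of 1.5-fold, 89.1% of 2-fold and 99.4% of 4-fold changes, with 8.5 false calls per simulation. The changed probe sets were drawn only from those above the median of probe means, so recovery of changes in dim genes was not tested. Noise was independent between arrays and between probe sets, so structure shared by samples was not simulated. Of simulated lists of 20 genes shifted by 0.3 on the log2 scale, 10 of 10 were found, and 3.4% of unshifted lists were called. These genes were simulated as independent. In the data the estimated correlation was 0.379 for DNA replication and 0.35 for MYC and ribosome biogenesis. The simulation therefore cannot give the rate of false calls for lists of correlated genes.

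The alternatives were the replicate number as a block, each of the 6 arrays left out in turn, cyclic loess normalization, scaling to a common median, only probe sets at or above the median of probe means, an intensity trend with robust eBayes, array weights, the average of the probe sets of each gene, and pseudocounts of 1 and 64. After the data had been seen, a restriction to probe sets paired with a gene and a fit with no further normalization were added. Every split of the 6 samples into 3 and 3 was also fitted. Figures were drawn with matplotlib 3.10.9.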

Results

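Gene expression was measured by microarray in mouse pro-B cells transformed with the v-Abl oncogene, a line arrested at an early stage of B cell development. The cells carried loxP-flanked alleles of Foxo1, a forkhead transcription factor required for early B cell development, and a Cre recombinase fused to the oestrogen receptor, which tamoxifen activates. The 3 untreated samples were compared with 3 samples treated with 1 µM tamoxifen for 2 days, and the question was which transcripts change when Foxo1 is deleted. Each of the 6 arrays gave an intensity for 34760 probe sets, with array medians between 100.9 and 109.1, and the number of arrays limits the precision. No label says that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All 6 samples had the same genotype, and tamoxifen-treated cells with intact Foxo1 were not analysed here.

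Foxo1 itself was lower in every tamoxifen sample. Its intensity was 806, 624 and 512 in untreated samples 1, 2 and 3 and 116, 151 and 134 in tamoxifen samples 1, 2 and 3. The mean was 647 ± 149 (SD, n = 3) in untreated cells and 134 ± 17.8 (SD, n = 3) after tamoxifen, a log2 fold change of -2.13 ± 0.15 (SE) with a limma adjusted p = 0.0178. Whether this probe set lies inside the deleted part of the gene is not given in the sources used here, so its fall is a check of the labels only as far as it does. The related factors Foxo3 and Foxo4 did not pass the test, with log2 fold changes of 0.10 ± 0.06 and 0.07 ± 0.09 (SE).

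Few transcripts passed the test between tamoxifen and untreated cells, and among those that passed Bank1, Ifi30 and Pld4 had the largest rises and Tgfb3 and Foxo1 the largest falls. With limma and Benjamini-Hochberg adjustment over 34760 probe sets, 20 passed an adjusted p of 0.05, of which 13 were raised and 7 were lowered. Of these, 8 changed at least 2-fold, 6 up and 2 down, and adjusted p ranged from 0.00794 to 0.0424. In each of the 20, the 3 tamoxifen values lay on one side of the 3 untreated values. Over all probe sets 9.89% had groups without overlap, where chance gives 10%. An unadjusted p under 0.05 was seen for 1775 probe sets.

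Among genes past the threshold, the largest rise was in Bank1, a B cell scaffold protein of antigen receptor signalling, from an intensity of 366 ± 73.6 to 1439 ± 163 (SD, n = 3), 3.82-fold on the log2(value + 16) scale. Ifi30, a lysosomal thiol reductase that prepares antigens for MHC class II, rose from 593 ± 61.4 to 1738 ± 62.3 (SD, n = 3), a log2 fold change of 1.52 ± 0.08 (SE) with a limma adjusted p = 0.00794. Pld4, an endolysosomal exonuclease, rose from 126 ± 9.31 to 355 ± 19.9 (SD, n = 3), 2.61-fold with a limma adjusted p = 0.012. Spib, an Ets-family transcription factor of B cells and plasmacytoid dendritic cells, rose from 155 ± 15.2 to 404 ± 33.8 (SD, n = 3), a log2 fold change of 1.29 ± 0.08 (SE) with a limma adjusted p = 0.0138. Bcar3, an adaptor protein, rose by a log2 fold change of 1.38 ± 0.10 (SE). Smaller rises were seen in Lsp1, a leukocyte actin-binding protein (1.05), Tnfrsf13c, the BAFF receptor (0.98), Atp2a3, a calcium pump of the endoplasmic reticulum (0.88), and Bcl11a, a transcription factor of early lymphoid cells (0.84). Ceacam1, a cell adhesion molecule, had a log2 fold change of 0.95, with its close paralog Ceacam2 at 1.03 and a limma adjusted p = 0.0732. Close paralogs can share signal on an array, so the values of Ceacam1 are uncertain.

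**Figure D1:**
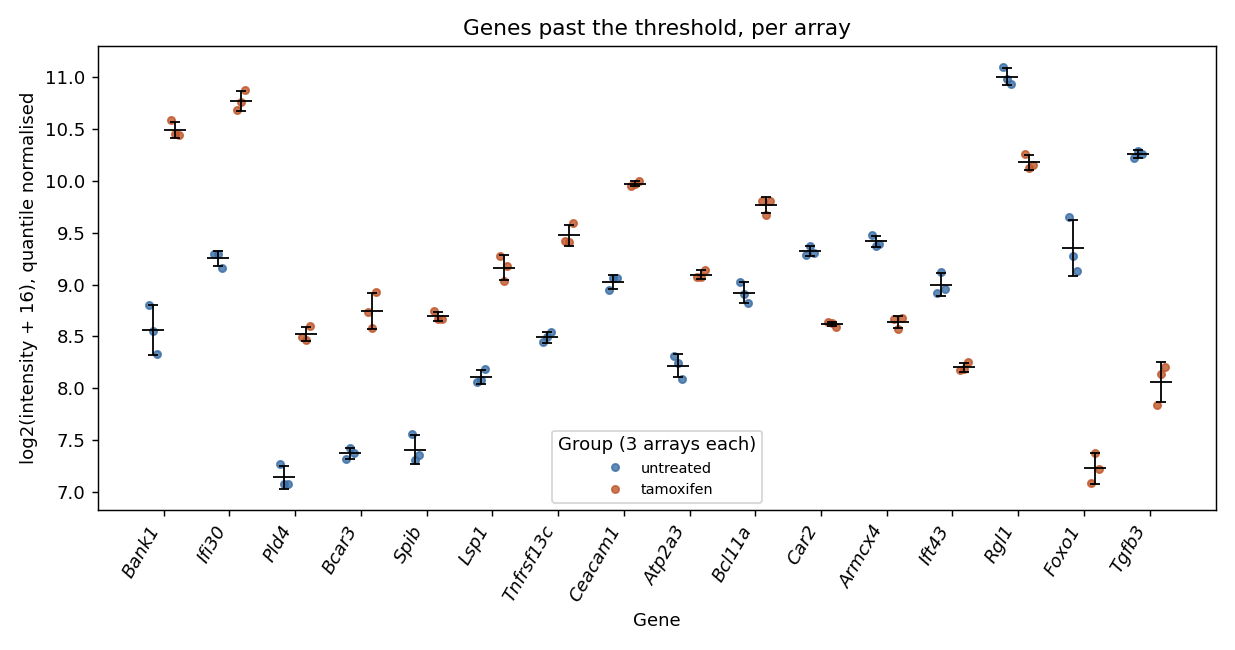
Log2(intensity + 16) after quantile normalization on the vertical axis for the 16 genes named by rule that passed an adjusted p of 0.05, ordered by log2 fold change. Points are single arrays (3 untreated in blue, 3 tamoxifen in orange), and bars give the mean and SD of each group. Groups do not overlap in any of these genes, from Bank1 (log2 fold change 1.93) to Tgfb3 (-2.19).

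Tgfb3, a ligand of the TGF-beta family, had the largest fall among genes past the threshold. Its intensity was 1204 ± 63.1 in untreated cells and 253 ± 31.2 after tamoxifen (SD, n = 3), a log2 fold change of -2.19 ± 0.10 (SE) with a limma adjusted p = 0.00794. The next of these genes downward after Tgfb3 and Foxo1 was Rgl1, an exchange factor for the small GTPase Ral, with a log2 fold change of -0.83 ± 0.07 (SE), from 2054 ± 199 to 1150 ± 124 (SD, n = 3). Ift43, a component of the intraflagellar transport machinery of cilia, had -0.79, Armcx4, an X-linked armadillo-repeat gene, -0.78, and Car2, a carbonic anhydrase, -0.70, with limma adjusted p between 0.0279 and 0.0424. Of the other calls, Ets1, a lymphoid transcription factor (0.72), and a RIKEN transcript, A530040E14Rik (0.86), rose but fell outside the rule for named genes, and were added after their values were seen. The RIKEN transcript has 3 probe sets, and the called one had intensities of 86.3 and 169 in untreated and tamoxifen cells. A brighter one (242 and 525) had a log2 fold change of 1.05 but a limma adjusted p = 0.0619. The remaining 2 called probe sets are not paired with a gene in the table used here.

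Apart from Foxo1, the measured FOXO and pro-B cell genes named in advance did not pass the test. Dntt, which encodes terminal deoxynucleotidyl transferase, measured 385 ± 165 in untreated cells and 144 ± 16.4 after tamoxifen (SD, n = 3), a log2 fold change of -1.26 ± 0.25 (SE) with a limma adjusted p = 0.365, and its groups did not overlap. Ebf1, a transcription factor that specifies the B lineage, had a log2 fold change of -0.51 ± 0.07 (SE) with a limma adjusted p = 0.169. It passed only where the probe sets of each gene were averaged and genes were tested, with a limma adjusted p = 0.0366 (range over all alternatives 0.0366 to 0.773). The recombinase genes Rag1 and Rag2 were dim on these arrays, with intensities of 68.7 ± 21.5 and 46.3 ± 20.8 in untreated cells and 52.5 ± 3.61 and 31.8 ± 5.20 after tamoxifen (SD, n = 3). Their log2 fold changes of -0.26 ± 0.19 and -0.32 ± 0.24 (SE) were within about 1 to 2 standard errors of 0, and without untreated sample 1 they were -0.05 and -0.05. Il7r, the receptor for interleukin-7, measured -0.09 ± 0.18 and Blnk, an adaptor of the pre-B cell receptor, 0.03 ± 0.11 (SE), and both changed sign under other settings. Pax5 (0.38), Igll1 (0.26), Vpreb1 (0.19), Klf2 (0.22), Ccnd2 (0.12) and Cdkn1b (0.13) had limma adjusted p of 0.736 or more. With 1 array left out Cdkn1b ran from 0.02 to 0.23, Ccnd2 from 0.05 to 0.20, Klf2 from 0.14 to 0.31 and Foxo4 from 0.02 to 0.13. A second probe set of Cdkn1b gave 0.10.

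**Figure D2:**
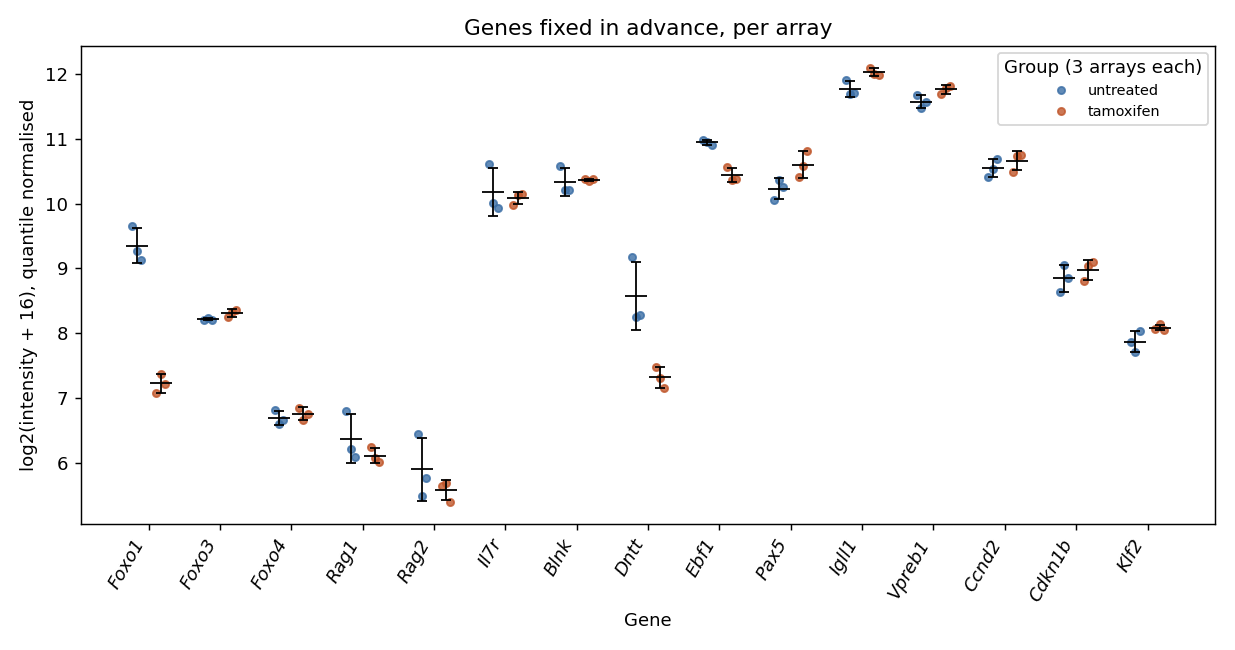
Log2(intensity + 16) after quantile normalization on the vertical axis for Foxo1 and the other 14 measured genes named in advance. Points are single arrays (3 untreated in blue, 3 tamoxifen in orange), and bars give the mean and SD of each group. Foxo1 passed the test (log2 fold change -2.13), and 7 genes lay apart without passing, Dntt and Ebf1 downward (-1.26 and -0.51) and Foxo3, Pax5, Igll1, Vpreb1 and Klf2 upward.

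Among 24 gene lists fixed in advance, 4 passed camera upward and 5 downward at the preset correlation. Pre-BCR and BCR signalling rose by camera with the preset correlation (16 of 21 measured members positive, median log2 fold change 0.15, adjusted p = 6.01e-06), with an adjusted p = 0.291 with an estimated correlation. Of its members 1 rose over all probe sets, Spib. Adjusted over the list alone 4 rose, Spib, Cd79b (0.52), Ptpn6 (0.53) and Pik3ap1 (0.54). Cd79b is a signalling chain of the B cell receptor, whereas Ptpn6 is a phosphatase that restrains it. B lineage regulators and markers also rose (20 of 29 positive, median 0.12, camera adjusted p = 0.00144), with an adjusted p = 0.297 with an estimated correlation. None of the 29 passed limma over all probe sets, and 14 had an unadjusted p under 0.05. Adjusted over the list alone 4 rose, Cd79b, Cd2, Il2ra (0.46) and Ms4a1 (0.40), and 2 fell, Ebf1 and Lef1 (-0.59), a transcription factor of early B cells. Ms4a1 was dim, with intensities of 22.6 ± 4.88 in untreated cells and 34.4 ± 2.16 after tamoxifen (SD, n = 3). The lowest lower quartile of any array was 43.3, so its rise is uncertain. The lymphocyte homing and egress list passed camera upward with as many members negative as positive (7 of 14 positive, median 0.03 with a 95% interval of -0.07 to 0.37, camera adjusted p = 0.011), with an adjusted p = 0.328 with an estimated correlation. In that list 0 of 14 passed limma over all probe sets, 3 had an unadjusted p under 0.05, and 2 rose adjusted over the list alone, the integrin chain Itgal (0.38) and the chemokine receptor Ccr7 (0.33). The homing call ended without untreated sample 1 (adjusted p = 0.205), without tamoxifen sample 3 (0.0573) and with dim probe sets left out (0.0695), and over all alternatives its adjusted p ran from 0.00118 to 0.328.

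Autophagy and lysosome genes rose as a group (20 of 24 positive, median 0.06, camera adjusted p = 0.000629), with an adjusted p = 0.384 with an estimated correlation. None of these members passed limma over all probe sets, 5 had an unadjusted p under 0.05, and Uvrag (0.34), a regulator of autophagosome maturation, rose adjusted over the list alone. The lysosomal genes Ctsd, Ctsa and Lamp2 measured 0.27, 0.26 and 0.18, whereas Ctsb, Ctsl and Lamp1 measured 0.01, 0.07 and -0.08.

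The lists of ribosome biogenesis, DNA replication and glycolysis passed camera downward. MYC and ribosome biogenesis genes fell (24 of 24 negative, median -0.13, camera adjusted p = 6.38e-05), with an adjusted p = 0.42 with an estimated correlation. Srm, which makes spermidine, measured -0.30 and Cad, of pyrimidine synthesis, -0.26. DNA replication and S phase genes fell (25 of 26 negative, median -0.12, camera adjusted p = 8.67e-05), with an adjusted p = 0.454 with an estimated correlation, and Pcna was the only positive member (0.22). Gins2 measured -0.35 and Mcm7 -0.23. In each of these lists limma called 0 members over all probe sets and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Glycolysis genes fell (16 of 19 negative, median -0.17, camera adjusted p = 6.38e-05), with an adjusted p = 0.291 with an estimated correlation. Over all probe sets limma called 0 of the 19, 5 had an unadjusted p under 0.05, and 1 fell adjusted over the list alone. That gene was Bnip3 (-1.01), a hypoxia-induced mitochondrial protein and not a glycolytic enzyme. The enzymes Tpi1 and Hk2 measured -0.45 and -0.36.

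Early-response genes fell as a list (14 of 22 negative, median -0.07, camera adjusted p = 0.0272), with an adjusted p = 0.291 with an estimated correlation. None of the 22 passed limma over all probe sets, 6 had an unadjusted p under 0.05, and Egr1 (-0.66) and Phlda1 (-0.64) fell adjusted over the list alone, while Btg2 measured 0.72. The early-response call ended without untreated sample 3 (adjusted p = 0.0921) and without tamoxifen sample 3 (0.0573), with a range of 0.00762 to 0.291 over all alternatives. Erythroid and megakaryocyte markers fell too (12 of 13 negative, median -0.08, camera adjusted p = 0.00302), with an adjusted p = 0.291 with an estimated correlation. Car2 fell over all probe sets and adjusted over the list alone. The other members lay between -0.13 and 0.04, and most of them were dim. In untreated and tamoxifen cells Klf1 (-0.13) had intensities of 56.4 and 49.3 and Gata1 (-0.09) 110 and 102, while the bright member Tfrc (-0.06) had 3127 and 2993.

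**Figure D3:**
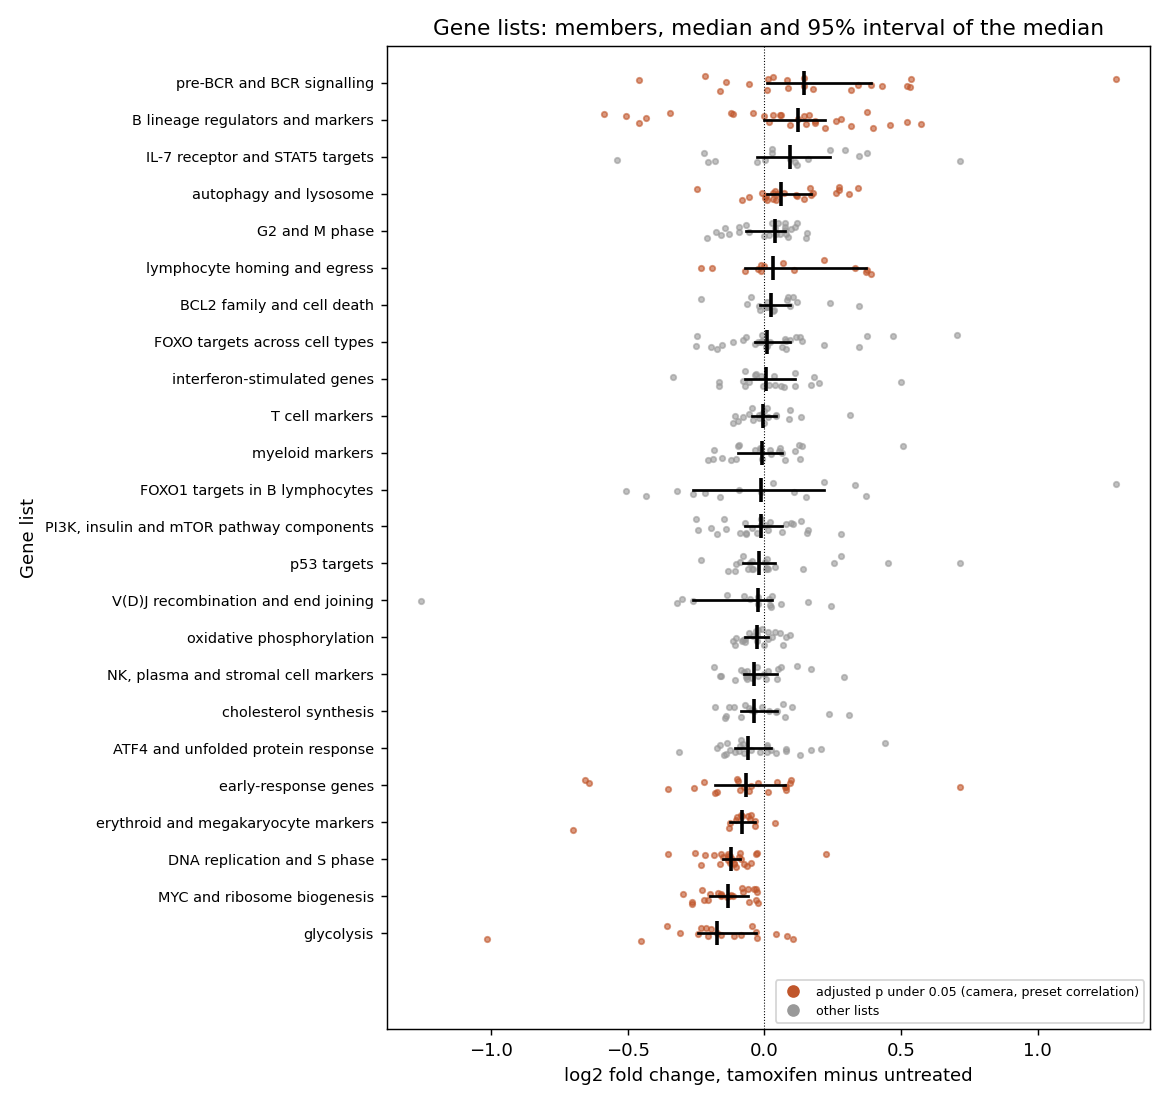
Log2 fold change (tamoxifen minus untreated) on the horizontal axis for the measured members of each of 24 gene lists. Points are genes, vertical bars the list medians and horizontal lines their 95% intervals, with lists past a camera adjusted p of 0.05 at the preset correlation in orange. The medians run from -0.17 (glycolysis) to 0.15 (pre-BCR and BCR signalling).

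The lists of FOXO targets did not pass camera. FOXO targets across cell types had 16 of 29 members positive (median 0.01, camera adjusted p = 0.0811). None of the 29 passed limma over all probe sets and 5 had an unadjusted p under 0.05, while Sesn3 (0.70), Rbl2 (0.38) and Klf6 (0.34) rose adjusted over the list alone. This list passed upward without untreated sample 2 (adjusted p = 0.00901), with a range of 0.00901 to 0.334 over all alternatives. FOXO1 targets in B lymphocytes had 7 of 15 positive, with a median of -0.01, a mean of 0.03 and a camera direction upward (adjusted p = 0.557). Spib rose over all probe sets, and adjusted over the list alone Spib and Ccr7 rose and Ebf1 fell. V(D)J recombination and end joining had 7 of 16 positive (camera adjusted p = 0.557), and adjusted over the list alone Dntt fell, with 0 of 16 past limma over all probe sets and 1 at an unadjusted p under 0.05. IL-7 receptor and STAT5 targets had 12 of 17 positive (camera adjusted p = 0.206). Over all probe sets limma called 0 of the 17, and 7 had an unadjusted p under 0.05. Adjusted over the list alone Cish (0.71) and Socs2 (0.29), both feedback inhibitors of cytokine signalling, rose and Pim2 (-0.54), a survival kinase, fell.

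The other 11 lists had no member past limma, either over all probe sets or adjusted over the list alone. For the cell cycle and stress lists, camera adjusted p was 0.684 for G2 and M phase, 0.557 for p53 targets, 0.516 for ATF4 and unfolded protein response, 0.206 for the BCL2 family and cell death and 0.684 for interferon-stimulated genes. At an unadjusted p under 0.05 these lists had 1, 3, 3, 1 and 2 members. Cholesterol synthesis had a camera adjusted p = 0.975, oxidative phosphorylation 0.684, and PI3K, insulin and mTOR components 0.837, with 0, 0 and 2 members at an unadjusted p under 0.05. Without tamoxifen sample 1, cholesterol synthesis passed upward (adjusted p = 0.000282) and oxidative phosphorylation downward (0.00632), where the highest values over all alternatives were 0.993 and 0.983. Markers of other cell types did not pass either, with camera adjusted p of 0.78 for T cells, 0.853 for myeloid cells and 0.614 for NK, plasma and stromal cells, and 0, 2 and 1 members at an unadjusted p under 0.05. Median, mean and camera direction differed in sign for p53 targets (median -0.02, mean 0.04, upward), cholesterol synthesis (-0.04, -0.01, upward), PI3K components (-0.01, -0.02, upward), T cells (-0.01, 0.01, upward) and myeloid cells (-0.01, 0.00, upward).

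The calls rest on few arrays. All 20 called probe sets kept their direction with any array left out, which groups without overlap leave little room to change. In these fits limma called 6 without untreated sample 1, 2 without tamoxifen sample 1, and 0 without untreated 2, untreated 3, tamoxifen 2 or tamoxifen 3. The fits with 0 calls had 2218, 1455, 1360 and 1518 probe sets at an unadjusted p under 0.05. With arrays scaled to a common median 85.7% of the calls were raised (12 of 14), and with no further normalization 83.3% (10 of 12), against 65% (13 of 20) after quantile normalization. With the replicate number as a block limma called 0 probe sets, with 2525 at an unadjusted p under 0.05. Whether the numbers pair the samples cannot be told here.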

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

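The fits on probe sets paired with a gene and with no further normalization were chosen after the data were seen. All 20 called probe sets kept their direction wherever they were tested. Across the alternatives of the 16 called named genes 142 of 272 values stayed past the threshold and 272 of 272 kept their sign. The kept signs carry little weight, because these groups did not overlap and several alternatives left the fold changes as they were. The main counts were 20 changed, 13 raised, 7 lowered and 8 at least 2-fold. With 1 array left out the counts ran from 0 to 6 changed, 0 to 4 raised, 0 to 2 lowered and 0 to 6 at least 2-fold. There were 6 calls without untreated 1, 2 without tamoxifen 1 and 0 otherwise, where limma gave at least 1360 at an unadjusted p under 0.05. Whether fewer samples alone account for these counts was not tested. Over the same fits the Foxo1 log2 fold change ran from -2.26 to -1.97, with limma adjusted p from 0.0276 to 0.156, and passed only without untreated 1. Under a replicate block limma called 0 (0 raised, 0 lowered, 0 at least 2-fold, with 2525 at an unadjusted p under 0.05), Foxo1 stayed at -2.13 with an adjusted p of 0.0936, and 8 lists passed. Whether the numbers pair the samples cannot be told here. Deviations of same-numbered samples were all positively correlated (0.256, 0.0547 and 0.302). However, untreated 2 correlated best with tamoxifen 1 (0.103), and untreated 3 correlated at 0.248 with tamoxifen 2. A shared batch or culture by number therefore stays open, and so does the block fit. Cyclic loess gave 20 changed (18 of the 20 calls kept), 14 raised, 6 lowered. Fewer were called with a common median (14, 12 raised, 2 lowered, 11 at least 2-fold, 10 kept), an intensity trend with robust eBayes (12, 9 raised, 3 lowered, 12 kept), a pseudocount of 1 (11, 9 raised, 2 lowered, 11 kept) and no further normalization (12, 10 raised, 2 lowered, 10 kept), and the cause was not tested. More were called with dim probe sets left out (46, 30 raised, 16 lowered, 19 at least 2-fold), array weights (39, 27 raised, 12 lowered, 16 at least 2-fold), gene averages (73, 42 raised, 31 lowered, 17 at least 2-fold) and probe sets paired with a gene (60, 40 raised, 20 lowered, 18 at least 2-fold), each keeping every main call tested. Apart from array weights, where the cause was not tested, these 4 fits made fewer tests, and unpaired probe sets had a median residual SD of 0.163 against 0.1 for paired ones. A pseudocount of 64 gave 22 (15 raised, 7 lowered), with Foxo1 at -1.83. With no array left out, Foxo1 had a limma adjusted p between 0.000712 and 0.0421 except under the block. Among uncalled named genes 2 changed sign in 4 alternatives, Il7r (0.12 without untreated 1, 0.00 with array weights) and Blnk (-0.03 without untreated 2 or untreated 3). Leaving out dim probe sets removed Rag1, Rag2 and Foxo4. Of gene lists 9 passed, and 7 to 11 with 1 array left out, 9 with cyclic loess or gene averages, 8 with dim probe sets left out, 10 with no further normalization, and 0 with an estimated correlation or with fry. FOXO targets passed without further normalization (camera adjusted p = 0.0403), and the early-response call ended under the block (0.0616). Dim probe sets limit what can be seen, as log2(value + 16) compresses their changes.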

Other observations

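The test of neighbouring genes and its restriction to fewer pairs were chosen after their results were seen. The lists of plasmacytoid dendritic cell, MHC class II and late B cell genes were written after the top genes were seen. Their members' values had not been seen by then. Adjusted p of camera and fry for these 3 lists were taken over the 3 lists alone, not with the 24 fixed lists.

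Further genes stood out where only probe sets paired with a gene were tested, and those named here were chosen after their values were seen. That fit called 60 probe sets, and the genes it added did not pass over all probe sets. Upward were Cd36, a scavenger receptor (log2 fold change 2.12 ± 0.20 SE, limma adjusted p = 0.00853, against 0.0504 over all probe sets), Cd74, the invariant chain of MHC class II (1.56 ± 0.20, 0.0292 against 0.132), Kmo, an enzyme of tryptophan breakdown (1.53 ± 0.16, 0.0118 against 0.0619), and Nucb2, a calcium-binding protein (1.07 ± 0.10, 0.00868 against 0.0504). The Fc receptor-like genes Fcrl1 (0.82) and Fcrla (0.50) and the transcription factor Lmo2 (0.74) were also raised. Downward were Sema6d, a semaphorin (-1.75 ± 0.24, 0.0446 against 0.184), Efhd1, a mitochondrial calcium-binding protein (-1.23), Gja1, a gap junction protein (-0.89), Ptger4, a prostaglandin E2 receptor (-0.76), and the Ets-family factor Etv5 (-0.60).

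Of the 10 splits of the 6 samples into 3 and 3, the real one gave 20 called probe sets and the highest of the others 0, so 1 split was as large, itself. With 10 splits the share cannot be under 0.05. At an unadjusted p under 0.05 the real split had 1775 probe sets, fewer than several others. The split of untreated 1, untreated 2 and tamoxifen 1 from the rest had 3535. That of untreated 1, untreated 3 and tamoxifen 3 had 2654, and that of untreated 1, tamoxifen 1 and tamoxifen 3 had 2478. These counts point to a structure of the samples other than treatment. The first principal component (32.3% of the variance) set untreated 1 and tamoxifen 1, which share a replicate number, on one side and the other samples on the other. On the second (26.8%) these 2 samples lay on opposite sides (-26.4 and 15.0). Whether the numbers pair the samples therefore stays open here too. The third component (18.7%) separated treated from untreated samples.

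The rise of Spib, Pld4, Ifi30, Bank1, Bcl11a, Tnfrsf13c and Lsp1 holds genes shared by B cells and plasmacytoid dendritic cells. Such dendritic cells in the treated cultures would bring their other transcripts too, but 16 measured markers had a median log2 fold change of 0.00325 (95% interval -0.06 to 0.14), with intensities of 105.9 and 108.1 for Siglech and 210.1 and 207.0 for Bst2, although camera gave an adjusted p = 0.0221 upward (adjusted p = 0.0702 with an estimated correlation, and fry adjusted p = 0.0133 upward), with Mpeg1 at 0.54, Tlr9 at 0.50 and Ly6d at 0.42. Of the 16 markers, 3 also stand in other lists. Myeloid cells are argued against in the same way by a median of -0.00792 over 23 markers (-0.10 to 0.06), with Lyz2 at 55.7 and 46.1 and Cd68 at 212.7 and 216.2, although Csf2rb, the brightest of them, measured 441 and 637 (log2 fold change 0.51). An effect of tamoxifen or Cre without Foxo1 loss cannot be told apart from Foxo1 loss, because 0 groups of tamoxifen-treated cells with intact Foxo1 were analysed. Loss of Foxo1, which the design names, therefore stays open as the biological explanation.

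These genes may be part of a wider shift towards a later B cell programme, a hypothesis found and tested on the same data. A list of MHC class II presentation genes without Cd74 and Ifi30 was raised by camera at the preset correlation (p = 7.02e-05). With an estimated correlation its camera p was 0.0156, or 0.0469 adjusted over 3 lists. Of its members 8 of 10 were positive. Among them were Ctss (0.41), with intensities of 2176 and 2893 in untreated and tamoxifen cells, and the dim H2-Aa (0.37), with 57.1 and 77.4. H2-Ob measured -0.29, with intensities of 866 and 709, and H2-Eb1 -0.07. A list of late B cell genes was raised by camera at the preset correlation (p = 1.86e-05), but the call was lost with an estimated correlation (adjusted p = 0.0635). By fry both lists moved upward on balance (adjusted p over 3 lists = 0.0133 for MHC class II and 0.0309 for late B cell genes). Their unadjusted fry p were 0.00883 and 0.0309. Among the 24 fixed lists, an unadjusted fry p of 0.00755 for pre-BCR and BCR signalling became 0.0906. The adjusted p of the 2 sets of lists are therefore not comparable. Of the late B cell genes 17 of 23 were positive, among them Cd180 (0.75), Swap70 (0.45) and Cd1d1 (0.41), while Blk measured -0.46. With limma 0 members of either list passed over all probe sets, where 3 and 9 had an unadjusted p under 0.05, and adjusted over the list alone 2 and 0 passed. Of the late B cell genes 4 also stand in the fixed lists, 3 of them in B cell lists. The dim gene Ms4a1 is among those that rose adjusted over the B lineage list alone. The late B cell list is therefore not independent evidence. The question of tamoxifen or Cre acting without Foxo1 loss applies here as well (0 such groups).

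Tgfb3 and Ift43, which lie beside each other in the RefSeq gene table, both fell, and Mybpc2 (0.75), beside Spib, was raised among paired probe sets. Whether neighbours of called genes may move with them was tested over 30 pairs, of which 17 moved the same way, with a mean signed log2 fold change of 0.0723 (one-sided permutation p = 0.0069) against 0.00802 for random genes. Without the pairs of Tgfb3 and Spib, which gave the idea, the mean over 26 pairs was 0.0252 (one-sided permutation p = 0.201). The low p over all pairs thus depended on those 4 pairs. Of the 26 other pairs 14 moved the same way, among them Ppp3ca (0.53) beside Bank1, whereas Fnbp1l (-0.46) lay beside the raised Bcar3. The Tgfb3 and Ift43 pair itself was not explained by any test run here.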
